A study of Homo sapiens with 9 samples.

How the data were processed

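Gene expression was measured in U87 cells, an established human glioma line, after transfection with a control duplex or with 1 of 2 forms of a microRNA, miR-376a*A (unedited) and miR-376a*G (edited). There were 9 Affymetrix human expression arrays in 3 groups of 3. Each array was placed in its group by its label. The labels describe the replicates as biological; they do not say which cultures, days or hybridisation batches they came from.

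Per the labels' protocols, cells received 50 nM of duplex with Lipofectamine RNAiMAX and were kept for 72 h. Total RNA was extracted with Trizol, purified once on a Qiagen column, spiked with poly-A control RNA ahead of oligo(dT) priming, amplified and labelled with biotin-ULS, per the labels' protocols. Intensities were made with GCOS 1.4.0.036, per the submitters' processing notes. The summarisation algorithm and its settings are not given in the sources used here. The authors deposited 1 linear intensity value for each of 54675 probe sets per array. The deposited values were already scaled, since the mean after trimming 2% at each end was close to 100 on every array. Scaling of this kind removes a change in total messenger RNA, so every difference is relative to the rest of the array. No 2 arrays held identical values.

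Genes were named from the platform's probe table. It listed 42898 probe sets, of which 41091 had a single gene and 1801 had several. The remaining 11777 were not listed there and were kept out of the gene tests, together with those of several genes. The named probe sets covered 19775 genes, of which 19735 were matched by Entrez number to the RefSeq gene table of assembly GRCh38.p14. The other 40 kept the probe table's symbol, and 0 symbols had to be updated. The source files state no genome build, so no coordinates are given. Among the probe sets counted above, 62 were control probe sets. In the gene lists 36 entries had no probe set in the probe table and were not analysed here. A second gene fixed for naming was among them. The result of 1 further list is not reported here.

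Values were tested as log2(signal + 1). Fold changes are therefore on the log2(signal + pseudocount) scale, which understates the change of dim genes. Each gene was represented by the probe set with the highest mean log2 value over the 9 arrays, without regard to group. This chose among several probe sets for 8254 of the tested genes. A gene was tested if its signal was above its array's median on at least 3 arrays, which kept 12587 genes. Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 9 arrays, with 1 coefficient per group, no covariate and 6 residual degrees of freedom. Moderated tests used eBayes with an intensity trend. A gene was called when its Benjamini-Hochberg adjusted p over all tested genes was under 0.05, separately in each of the 3 comparisons. All adjusted p-values below come from these limma models and are two-sided. A moderated F test gave the genes differing among the 3 groups.

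Gene lists, the rule for naming genes and the first set of other settings were written before the data were examined. Each list with at least 5 tested members was tested against all other genes with limma's camera at a preset correlation of 0.01. Its p-values were adjusted over the lists of a comparison and given again with a correlation estimated from the data. Members are also counted after adjustment over the list alone. The genes named in each comparison were the intended targets, the 10 genes with the largest change in each direction among called genes whose 3 arrays of one group all lay beyond the 3 of the other, and the 4 members of each list with the smallest p. Where no gene passed, the 5 with the smallest p were named instead. Genes known only by a locus number were passed over. Tests of seed matches, also planned, need 3′ UTR sequences and were not run. The fold changes of the 2 microRNA comparisons share their control arrays, so their correlation was set beside 100 simulated draws of unchanged groups.

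The same steps were tested on simulated data with the spread between arrays of the real groups, with 50 genes changed at each of 4 fold sizes. For miR-376a*A against control, 16% of genes changed 1.5-fold, 50% of those changed 2-fold and 92% of those changed 4-fold were recovered. The shares were 18%, 58% and 86% for miR-376a*G against control, and 16%, 66% and 98% for miR-376a*A against miR-376a*G. With the smaller spread of the miR-376a*G arrays, 70%, 96% and 100% were recovered for miR-376a*A against control at the same group size, so the spread within the labelled groups lowers recovery. The simulation drew genes independently and gave the full change to all 3 arrays of a group. It therefore does not give recovery where arrays of a labelled group differ in the change they carry. The arrays labelled miR-376a*A replicate 1 and control replicate 1, described below, may be such a case. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1. Median signal ranged from 18.0 to 24.6 over the arrays.

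That set covered the filter, the normalization (quantile normalization, or centring each array on its median), pseudocounts of 16 and 64, the replicate number as a block, limma's array weights, the variance trend, the probe sets of a gene, the arrays in the fit, the threshold and leaving out each array in turn. Added after the arrays had been seen were scaling to the hybridisation controls, scaling to the poly-A controls, and leaving out the arrays labelled miR-376a*A replicate 1 and control replicate 1 together, which leaves 4 residual degrees of freedom. The labels do not say what same-numbered arrays share, so the numbers were not used as pairs. Such arrays did not deviate together, but between miR-376a*A and control the arrays just named could mask a shared deviation. Plots and exact tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The R package statmod 1.5.0 was loaded with limma. The replicate block was a fixed effect in the model.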

Results

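Transcript levels were measured in U87 glioma cells 72 h after transfection with 50 nM miR-376a*A, miR-376a*G or a control duplex, with 3 arrays per group. miR-376a* is a microRNA whose precursor can be edited from adenosine to inosine, which pairs like guanosine. The A and G duplexes stand for its unedited and edited forms. The design set each form against the control, and the 2 forms can also be set against each other. Median signal was 19.5 ± 1.55 (SD, n = 3) on the arrays labelled miR-376a*A, 23.3 ± 1.44 on those labelled miR-376a*G and 19.8 ± 1.98 on those labelled control.

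RAP2A, a small GTPase of the RAS family, was named in advance as a presumed target of the unedited form from general knowledge, since the labels name no target. Its signal overlapped between the groups labelled miR-376a*A and control. For the brighter of its probe sets, signal on the arrays labelled miR-376a*A replicates 1, 2 and 3 was 895, 412 and 531. On those labelled control it was 353, 702 and 784, and on those labelled miR-376a*G it was 899, 888 and 863. The group means were 612 ± 252, 613 ± 229 and 883 ± 18.2 (SD, n = 3). A second probe set gave 735, 375 and 578 for miR-376a*A, 329, 592 and 792 for control, and 562, 615 and 571 for miR-376a*G. The gene's 3 other probe sets were dim, with group means of 1.10 to 49.6, and were not called where tested. In log2 terms RAP2A differed by 0.00 (SE 0.33, adjusted p = 0.997) between miR-376a*A and control, by 0.61 (adjusted p = 0.194; 0.25 without the array labelled control replicate 1) between miR-376a*G and control, and by -0.60 (adjusted p = 0.183) between miR-376a*A and miR-376a*G.

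**Figure D1:**
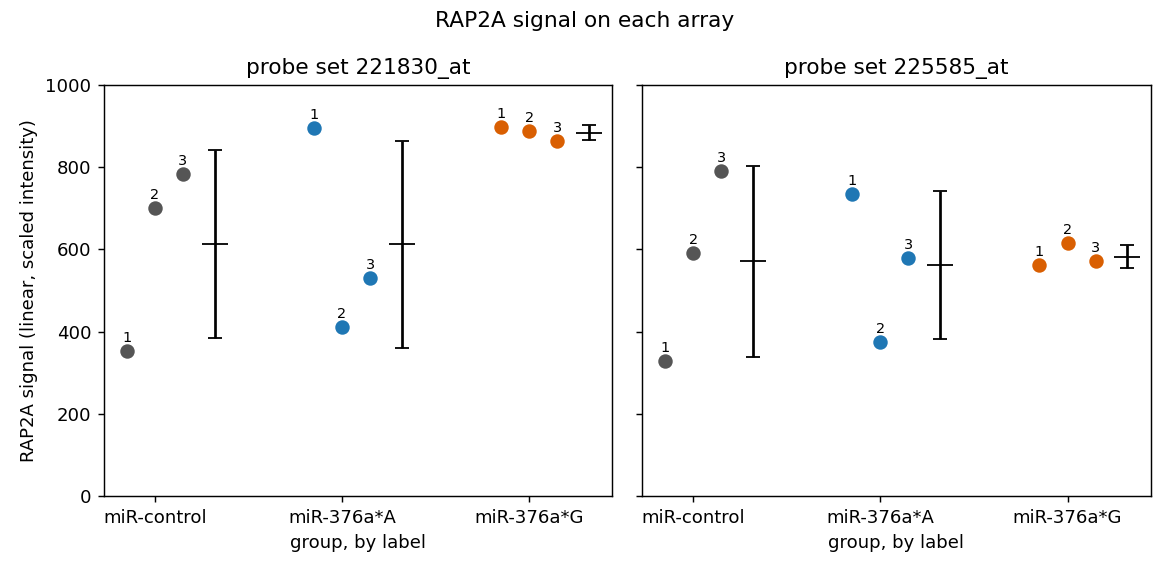
RAP2A signal (linear scaled intensity) on each array for the 2 brightest of its 5 probe sets, by labelled group; points are arrays, numbered by replicate, and bars give the group mean ± SD (n = 3). In the left panel the array labelled miR-376a*A replicate 1 (895) lies above all 3 labelled control, and the array labelled control replicate 1 (353) lies below all 3 labelled miR-376a*A.

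The same 2 arrays stood apart over all tested genes. The array labelled miR-376a*A replicate 1 correlated at r = 0.987 and 0.990 with control replicates 2 and 3, and at 0.925 and 0.934 with miR-376a*A replicates 2 and 3 (Pearson's r across genes, which are not independent replicates). The array labelled control replicate 1 correlated at 0.990 and 0.982 with miR-376a*A replicates 2 and 3, and at 0.935 and 0.933 with control replicates 2 and 3. Pairs of arrays labelled miR-376a*G correlated at 0.986 to 0.988. The mean levels of the spiked controls did not cross in this way. Hybridisation controls had a mean log2 signal of 7.85 ± 0.06 (SD) on the arrays labelled miR-376a*A, 7.58 ± 0.10 on those labelled control and 7.17 ± 0.09 on those labelled miR-376a*G, and no array of one labelled group lay within another. The 3′ to 5′ log2 ratio of the spiked control Dap did not keep to the labels, at 1.93, 2.55 and 2.44 on miR-376a*A replicates 1 to 3 and 2.41, 2.16 and 2.28 on control replicates 1 to 3. Because of these values, groups are given below as the arrays are labelled, and the number of genes called in each comparison is given again without those 2 arrays, a choice made after seeing the data.

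**Figure D2:**
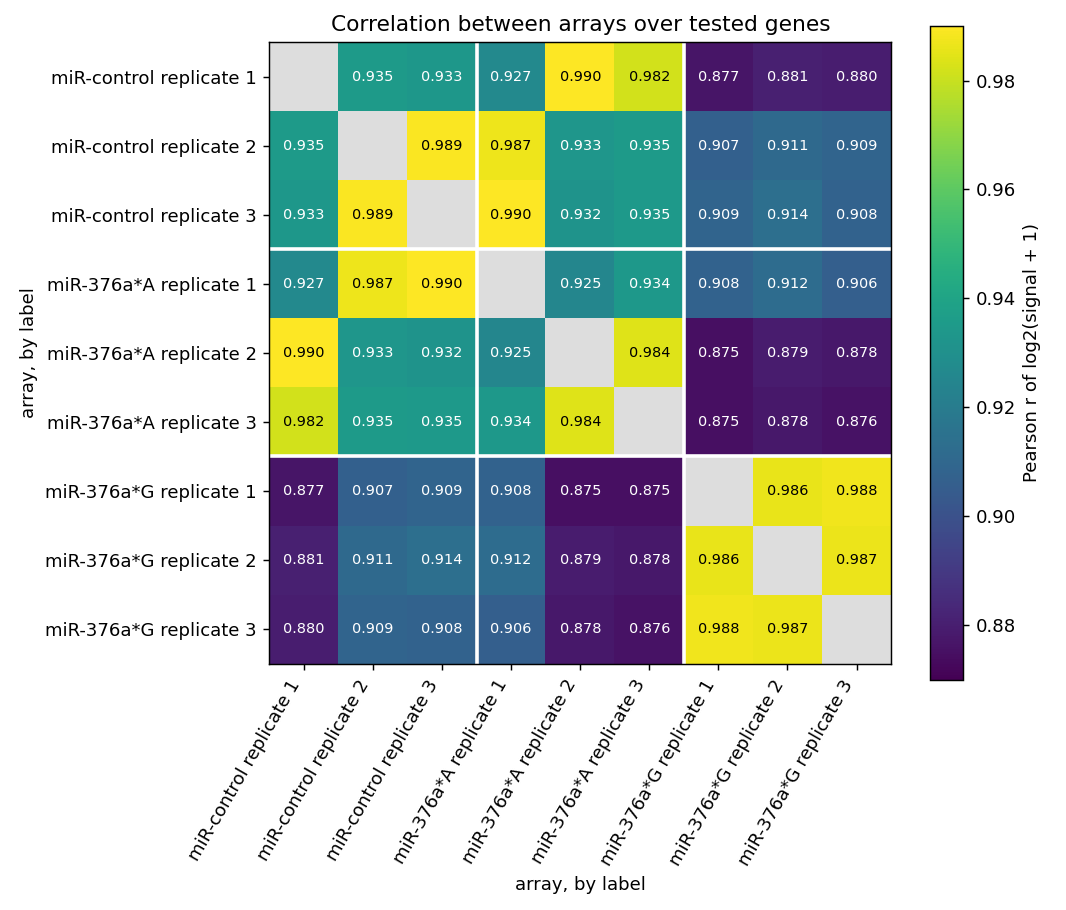
Pearson's r of log2(signal + 1) over the tested genes for each pair of arrays, arranged by label; both axes list the 9 arrays and the colour gives r. The array labelled miR-376a*A replicate 1 is closest to control replicates 2 and 3 (0.987 and 0.990), and the array labelled control replicate 1 to miR-376a*A replicates 2 and 3 (0.990 and 0.982).

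In the comparison of miR-376a*A with control, which asks what the unedited form changes, no single gene passed the test as the arrays are labelled. The genes with the smallest p were NKAP (log2 difference -0.69), the antisense transcript ASH1L-AS1 (-0.74), OOEP (-2.38), the mitochondrial ribosomal gene MRPL2 (-0.72) and SMDT1 (-0.40), a regulator of the mitochondrial calcium uniporter, all with an adjusted p of 0.886. Members of 5 gene lists lay higher than other genes at the preset correlation. These were hypoxia and glycolysis (27 tested, median 0.16, adjusted p = 2.8e-06), mesenchymal and matrix genes (25, 0.30, 7.3e-06), housekeeping genes (14, 0.19, 7.3e-06), integrins and focal adhesion (22, 0.12, 0.0077) and growth factor receptors and glioma pathway genes (33, 0.11, 0.0446). No member of any of these lists was called, over all genes or adjusted over the list alone. With an estimated correlation none of the 5 held, at an adjusted p = 0.552 for housekeeping genes and an adjusted p = 0.573 for each of the others. Among their members, SPARC differed by 0.34, VIM by 0.24, LDHA by 0.28 and ITGB3 by 0.38. Medians of the other lists tested lay between -0.15 for interferon-stimulated genes and 0.14 for proteases and their inhibitors. The housekeeping list lost its preset-correlation call without both arrays that stood apart (adjusted p = 0.0748). The integrin list lost it without miR-376a*A replicate 3 (adjusted p = 0.237) or control replicate 3 (0.0722), and the growth factor list without any one of miR-376a*A replicates 2 or 3, miR-376a*G replicates 2 or 3, or control replicates 2 or 3 (0.245, 0.237, 0.0515, 0.0503, 0.146 and 0.401). Scaling to the hybridisation controls moved all genes alike, their median to -0.29 and the medians of these 5 lists to -0.11, 0.02, -0.08, -0.15 and -0.16 in the order given.

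Of 12587 genes, 0 were called by limma between miR-376a*A and control as labelled, and 463 had an unadjusted p under 0.05. With the labels kept and arrays weighted by limma, 5513 were called. The weights were 0.154 for miR-376a*A replicate 1 and 0.165 for control replicate 1, against 0.674 to 2.93 for the other arrays. That count therefore rests little on those 2 arrays and is not separate from the count without them. Without the arrays labelled miR-376a*A replicate 1 and control replicate 1 the count was 5269, with 2389 higher and 2880 lower, and RAP2A differed by -0.66 (SE 0.12, adjusted p = 9.9e-04). Those p-values are not independent of the choice of arrays. Leaving out either of the 2 alone still gave 0 genes, and raised the number of lists passing at the preset correlation from 5 to 9 each time.

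In the comparison of miR-376a*G with control, which asks what the edited form changes, 31 of 32 tested G2/M genes rose, while 19 of 27 hypoxia and glycolysis genes and 12 of 22 integrin and focal adhesion genes fell. As lists these 3 passed at the preset correlation but not with an estimated one (adjusted p = 0.213, 0.213 and 0.244). CSF3, which encodes a granulocyte growth factor, rose from a mean log2 signal of 6.74 to 10.84, a difference of 4.10 (SE 0.50, adjusted p = 3.9e-04). PPL, encoding the cytoskeletal linker periplakin, fell by 5.28 on the log2 scale (SE 0.18, adjusted p = 1.7e-06), and DEPP1 fell by 4.78 (SE 0.27, adjusted p = 1.0e-05). ITGB3, the integrin β3 subunit, fell by 3.29 (SE 0.13, adjusted p = 1.7e-06), and PDK1, a pyruvate dehydrogenase kinase, fell by 2.62 (SE 0.10, adjusted p = 1.7e-06). The further genes with the largest increases were SPRR2B (4.46), FBXO43 (3.61), FABP4 (3.12), the condensin subunit NCAPH (3.03), GPM6A (2.98), SYNPO2L (2.97), ARHGAP11A (2.94), the tight junction gene CLDN1 (2.90) and the centromere gene CENPM (2.79). Those with the largest decreases included the transcription factor NFATC2 (-5.02), EFCAB13-DT (-4.26), CNGA3 (-4.08), ST8SIA5 (-3.99), SLITRK6 (-3.84), APCDD1L (-3.78), KCTD21 (-3.76) and the chemokine receptor ACKR3 (-3.74). Part of some sizes came from control replicate 1, an array that stood apart. Its signals for CNGA3, ST8SIA5, SLITRK6 and APCDD1L were 128, 429, 144 and 291. Control replicates 2 and 3 gave 21.2 and 13.7, 129 and 81.4, 28.6 and 36.9, and 129 and 124. For NCAPH it gave 13.3, against 58.1 and 47.8. Several were dim on one side, so the order in both directions depends on the pseudocount. With a pseudocount of 16 SPRR2B changed by 1.95, FBXO43 by 2.04, FABP4 by 1.53 and SYNPO2L by 1.22. CSF3 then changed by 3.90, CENPM by 2.59, NCAPH by 2.52 and CLDN1 by 2.35. Among decreases DEPP1 was at -3.69, EFCAB13-DT at -3.52, PPL at -3.05, ST8SIA5 at -2.83, APCDD1L at -2.73 and NFATC2 at -2.62. SLITRK6 was at -1.92, KCTD21 at -1.78 and ACKR3 at -1.49, while CNGA3 was no longer called (-1.67, adjusted p = 0.0823). SLITRK6 was not called with a pseudocount of 64 (-0.89, adjusted p = 0.0597).

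Cell cycle lists moved furthest upward. Of 32 tested genes of G2/M and mitosis, 31 rose and 0 fell (32 and 0 adjusted over the list alone), with a median of 1.78 (adjusted p = 4.7e-16, and adjusted p = 0.213 with an estimated correlation). The mitotic kinase gene PLK1 rose by 2.59, the cyclin gene CCNB2 by 2.01, the topoisomerase gene TOP2A by 2.15 and BIRC5, encoding survivin, by 1.88. Of 34 genes of G1/S and DNA replication, 29 rose and 0 fell (31 and 1 over the list alone), with a median of 1.47 (adjusted p = 5.4e-15). With an estimated correlation it also held (adjusted p = 0.0081), but not without the 2 arrays that stood apart (adjusted p = 0.151), where the median was again 1.47 and 33 of 34 were called higher. The transcription factor genes E2F2 and E2F8 rose by 2.77 and 2.31, the replication licensing gene CDT1 by 2.26 and the ribonucleotide reductase gene RRM2 by 1.49. Of 21 genes of NF-kB signalling and inflammatory cytokines, 11 rose and 2 fell over all genes and over the list alone, with a median of 0.62 (adjusted p = 0.0042, and adjusted p = 0.213 with an estimated correlation). Their largest calls by p were the chemokine genes CXCL1 (2.55) and CXCL3 (2.09) and the cytokine genes LIF (1.77) and IL1A (2.25).

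Of 27 genes of hypoxia and glycolysis, 19 fell and 0 rose over all genes and over the list alone, with a median of -1.23 (adjusted p = 2.5e-13, and adjusted p = 0.213 with an estimated correlation). Besides PDK1, the glucose transporter gene SLC2A1 fell by 2.22 and the mitophagy receptor gene BNIP3L by 1.34. Of 22 integrin and focal adhesion genes, 12 fell and 0 rose (15 and 0 over the list alone), with a median of -0.75 (adjusted p = 4.8e-07, and adjusted p = 0.244 with an estimated correlation). Vinculin (VCL) fell by 1.56, the integrin activator gene FERMT2 by 1.26 and ITGB5 by 0.96. Of 25 mesenchymal and matrix genes, 10 fell and 2 rose (11 and 2 over the list alone), with a median of -0.64 (adjusted p = 0.0010, and adjusted p = 0.543 with an estimated correlation). Without control replicate 1, and so without both arrays that stood apart, that median was -0.38. The transcription factor gene SNAI2 fell by 2.13, the collagen gene COL5A1 by 2.45, fibronectin (FN1) by 1.32 and TGFBI by 0.82. The cell cycle and NF-kB lists stayed higher, and the hypoxia, integrin and mesenchymal lists lower, under all 4 other scalings tried. On the same arrays the log2 ratio of the 3′ to the 5′ control probe sets of GAPDH differed by -0.0733 from control (exact permutation p = 0.1, two-sided, the smallest that 3 arrays against 3 allow).

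Smaller list shifts lost their calls under some settings. Of 23 genes of ER-associated degradation, 6 fell and 3 rose (9 and 3 over the list alone), with a median of -0.22 that turned to 0.18 and 0.08 when arrays were scaled to the hybridisation or poly-A controls, which moves all genes alike and leaves the list at -0.34 from the median of all genes (adjusted p = 0.0451, and adjusted p = 0.543 with an estimated correlation). HERPUD1, which helps clear misfolded proteins from the ER, fell by 1.29, the mannosidase-like gene EDEM2 by 1.24 and the lectin gene OS9 by 1.30, while the ubiquitin-conjugating enzyme gene UBE2J2 rose by 0.80. That list lost its call without any one of 5 arrays, namely miR-376a*A replicates 1 (adjusted p = 0.0515) and 3 (0.0519), miR-376a*G replicates 1 (0.0758) and 3 (0.0668) and control replicate 3 (0.153), and with quantile normalization (0.121). Of 21 proteases and inhibitors of matrix invasion, 6 fell and 1 rose over all genes and over the list alone, with a median of -0.28 that turned to 0.12 and 0.02 under the same 2 scalings, again at -0.40 from the median of all genes (adjusted p = 0.0444, and adjusted p = 0.223 with an estimated correlation). The metalloprotease gene MMP16 rose by 0.92, and ADAM10 fell by 0.74 but was not called under either of those scalings (adjusted p = 0.0734 and 0.0566). The protease list lost its call without miR-376a*G replicate 1 (adjusted p = 0.0685) or control replicate 1 (0.0808).

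Other lists did not pass between miR-376a*G and control, although some members were called. In the unfolded protein response list 4 of 24 genes rose and 2 fell (median 0.10, adjusted p = 0.782), with the asparagine synthetase gene ASNS at 1.87 and the ER stress sensor gene ATF6 at -2.12. Interferon-stimulated genes gave 3 of 25 higher and 6 lower (median -0.29, adjusted p = 0.0734), with OASL at -1.46 and IFI6 at -2.17. Among growth factor receptors and glioma pathway genes 2 of 33 rose and 8 fell (median -0.32, adjusted p = 0.0846), with the TGF-β receptor gene TGFBR1 at -1.92 and FGF5 at 1.93. The p53 and apoptosis list had 3 of 23 higher and 4 lower (median -0.10, adjusted p = 0.419), with the death receptor gene TNFRSF10B at -1.32 and MDM2 at 1.11, for which another probe set was called the opposite way. In the list of small RNA machinery and RNA editing 3 of 15 rose and 2 fell (median 0.16, adjusted p = 0.952), with ADAR, which encodes an RNA editing enzyme, at -1.13 and AGO2, which encodes the slicing Argonaute protein, at 1.55. Oxidative phosphorylation had 4 of 23 higher and 1 lower (median 0.08, adjusted p = 0.721), with the succinate dehydrogenase gene SDHD at -1.90 and CYC1 at 0.71. Cholesterol genes had 2 of 19 higher and 3 lower (median 0.03 and mean -0.06, adjusted p = 0.677), with INSIG2, an inhibitor of sterol synthesis, at -1.70. Housekeeping genes had 1 of 14 higher and 2 lower (median 0.00, adjusted p = 0.721, with the test's sign opposite to the median's). Adjusted over the list alone these counts were the same, except for 3 and 1 in oxidative phosphorylation and 0 and 0 in housekeeping genes. Without both arrays that stood apart, of which only control replicate 1 enters these differences, the median turned to 0.12 for the p53 list and -0.05 for the cholesterol list and was -0.06 for the growth factor list (8 and 7, 4 and 5, and 9 and 11 higher and lower). Markers of other cell types were few on these arrays. Of 6 neuronal markers 1 rose and 2 fell (median -0.58, or -0.08 without both arrays that stood apart, adjusted p = 0.419), with SYT1 at -1.12 and MAP2 at -2.23, and of the 4 astrocyte, 3 oligodendrocyte, 3 endothelial, 1 epithelial and 2 leukocyte markers tested, 1, 1, 1, 0 and 0 rose and 2, 0, 0, 0 and 0 fell.

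Between miR-376a*G and control 4205 of 12587 genes were called, 2268 higher and 1937 lower. Without the 2 arrays that stood apart 7067 were called, 3925 higher and 3142 lower, of which 4189 were among the 4205 and had the same direction. The split depended on scaling. The median of all genes was 0.12 as deposited, -0.07 after centring arrays on their medians, 0.52 after scaling to the hybridisation controls and 0.42 after scaling to the poly-A controls. Centring on the medians gave 1285 higher and 2462 lower, so that 34.3% of calls were higher against 53.9% as deposited. The share was 85.8% with the hybridisation controls and 81.0% with the poly-A controls.

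**Figure D3:**
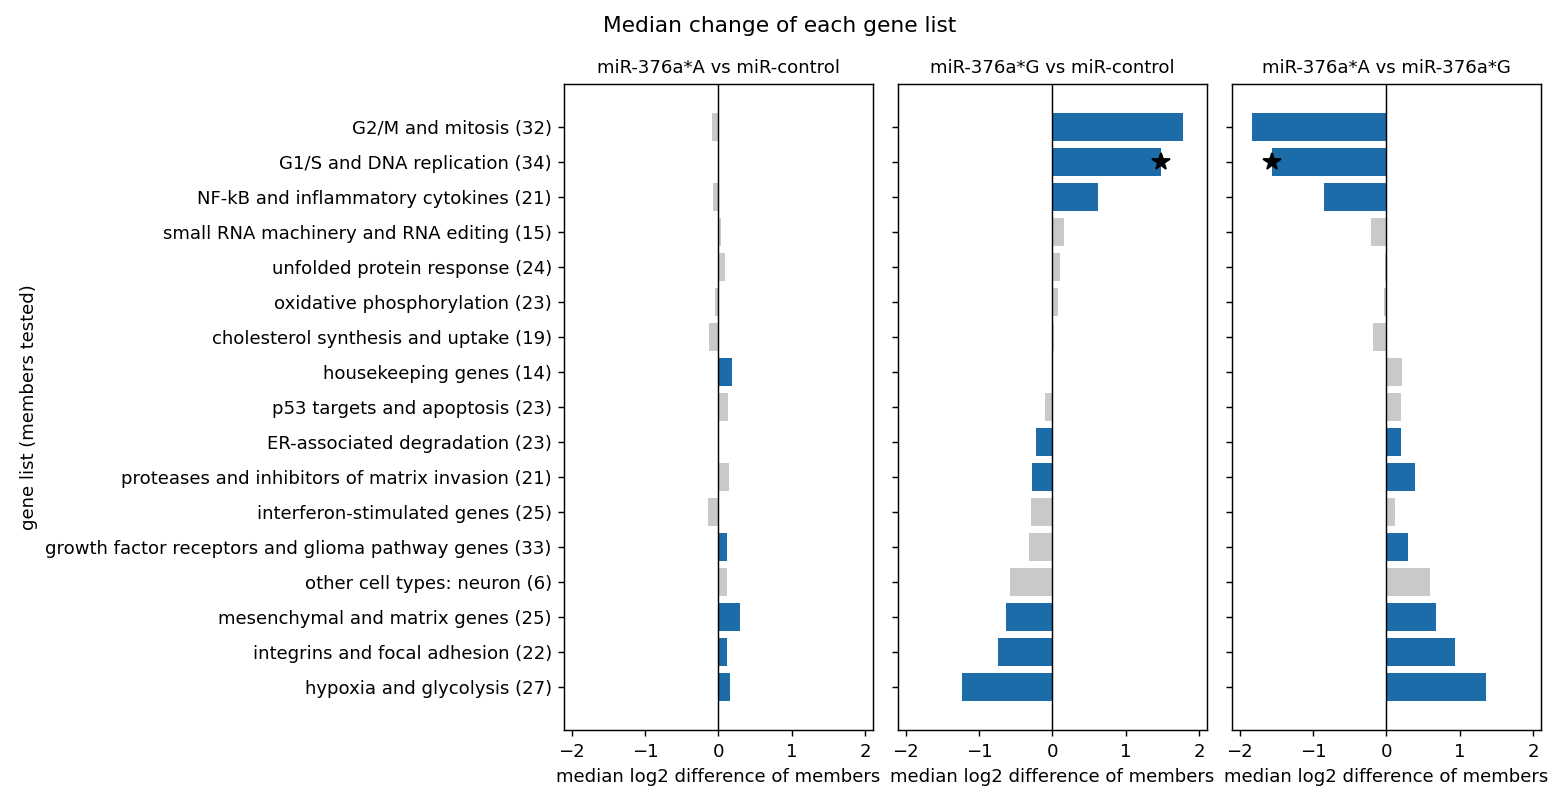
Median log2 difference of the tested members of each gene list reported (number tested in brackets) in the 3 comparisons as labelled. Blue bars passed the list test at the preset correlation (adjusted p under 0.05), grey bars did not, and stars mark lists that also passed with an estimated correlation, which was G1/S and DNA replication against control (1.47) and between the forms (-1.56).

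Set directly against each other, the 2 forms differed in cell cycle, hypoxia and adhesion genes, among others. As lists G2/M, hypoxia and integrins passed only at the preset correlation (adjusted p = 0.167, 0.149 and 0.200 with an estimated one). Cells labelled miR-376a*A had higher PPL (log2 difference 5.41, SE 0.18, adjusted p = 1.2e-06), DEPP1 (4.73, SE 0.27, adjusted p = 8.9e-06), ITGB3 (3.67, SE 0.13, adjusted p = 1.2e-06) and TIMP3 (4.14, SE 0.77, adjusted p = 0.0030), an inhibitor of matrix metalloproteases, and lower CSF3 (-4.02, SE 0.50, adjusted p = 3.8e-04) than cells labelled miR-376a*G. Other large positive differences were CNGA3 (4.80), ST8SIA5 (4.76), SLITRK6 (4.64), NFATC2 (4.64), GOLGA7B (4.49), APCDD1L (4.06) and MAP7D2 (4.01). Large negative ones were SPRR2B (-3.86), BEX5 (-3.67), CLDN1 (-3.45), FBXO43 (-3.45), GPM6A (-3.22), the DNA repair gene XRCC3 (-3.16), the kinetochore gene CENPU (-3.05), OIP5 (-3.04) and CENPM (-2.95). CENPU was not called without miR-376a*A replicate 2 (adjusted p = 0.0507) or replicate 3 (0.0562). CNGA3 was not called with a pseudocount of 64 (1.03, adjusted p = 0.0593), and the other members of both groups kept their calls. Dim genes had smaller values, such as 3.17 for PPL and -1.85 for SPRR2B at a pseudocount of 16, which changed the order. XRCC3 was then at -1.36, against -2.83 for CENPU, -2.64 for OIP5 and -2.73 for CENPM. For many of these genes miR-376a*A replicate 1, an array that stood apart, lay closer to miR-376a*G than replicates 2 and 3 did. Signals on replicates 1, 2 and 3 were 14.8, 90.6 and 128 for CNGA3, 87.3, 488 and 524 for ST8SIA5 and 273, 1520 and 1783 for TIMP3. They were 334, 62.7 and 54.8 for CENPU and 114, 28.2 and 29.6 for OIP5. Replicate 1 lay further off for NFATC2, SPRR2B and CSF3.

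All 32 tested genes of G2/M and mitosis were lower with miR-376a*A than with miR-376a*G, over all genes and over the list alone (median -1.83, adjusted p = 2.2e-15, and adjusted p = 0.167 with an estimated correlation), among them CDC20 (-2.86), PLK1 (-2.62) and UBE2C (-1.35). Of 34 G1/S and DNA replication genes 29 were lower and 1 higher in both counts (median -1.56, adjusted p = 9.8e-13, and adjusted p = 0.0133 with an estimated correlation, but 0.0864 without the 2 arrays that stood apart, where the median was -1.64), among them E2F2 (-2.74), CDT1 (-2.48) and GINS2 (-2.34). Hypoxia and glycolysis genes were higher, with 22 of 27 called and 0 lower (24 over the list alone; median 1.36, adjusted p = 1.1e-15, and adjusted p = 0.149 with an estimated correlation), among them PDK1 (2.74) and SLC2A1 (2.37). Of 22 integrin and focal adhesion genes 16 were higher and 0 lower (17 and 1 over the list alone; median 0.93, adjusted p = 5.8e-08, and adjusted p = 0.200 with an estimated correlation). Of 25 mesenchymal and matrix genes 13 were higher and 2 lower (14 and 2 over the list alone; median 0.67, or -0.01 when scaled to the hybridisation controls, both 0.81 from the median of all genes, adjusted p = 5.9e-06, and adjusted p = 0.410 with an estimated correlation), with SNAI2 at 2.27 and COL5A1 at 2.81. NF-kB and cytokine genes were lower in 12 of 21 cases and higher in 2 (13 and 2 over the list alone; median -0.85, adjusted p = 0.0032, and adjusted p = 0.149 with an estimated correlation), with CXCL1 at -2.88 and LIF at -1.79.

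Proteases and their inhibitors were higher with miR-376a*A in 11 of 21 cases and lower in 2 (median 0.39, adjusted p = 0.0093, and adjusted p = 0.149 with an estimated correlation), ER-associated degradation genes higher in 8 of 23 and lower in 3 (0.19, 0.0174 and 0.410), and growth factor and glioma pathway genes higher in 11 of 33 and lower in 2 (0.29, 0.0174 and 0.441), with the same counts over each list alone. These 3 medians turned to -0.29, -0.48 and -0.38 when arrays were scaled to the hybridisation controls, staying at 0.53, 0.34 and 0.44 from the median of all genes. For the growth factor list, mean log2 signal minus its 9-array mean was -0.15 on the array labelled miR-376a*A replicate 1. That lay within the miR-376a*G arrays (-0.30 to -0.11), while miR-376a*A replicates 2 and 3 were at 0.36 and 0.35. The ER-associated degradation list lost its call without the array labelled miR-376a*A replicate 1 (adjusted p = 0.0665) and without both arrays that stood apart (adjusted p = 0.125). HERPUD1 was higher by 1.49, but not called with the mean of its probe sets (0.72, adjusted p = 0.0600). TGFBR1 was higher by 1.96 and TGFB2 by 2.08, and FGF5 was lower (-1.97). The remaining tested lists did not pass, with adjusted p-values from 0.0508 for housekeeping genes (median 0.21) to 0.992 for cholesterol genes (median -0.18) and for small RNA machinery and RNA editing (median -0.21). The unfolded protein response (median -0.02) and cholesterol lists had a test of positive sign against a negative median. Without both arrays that stood apart the unfolded protein response median turned to 0.10, and the p53 list passed at the preset correlation (median 0.41, adjusted p = 0.0137, and adjusted p = 0.104 with an estimated correlation).

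Between the 2 forms 4804 of 12587 genes were called, 2065 higher and 2739 lower with miR-376a*A. Without the 2 arrays that stood apart the count was 7508, with 3231 higher and 4277 lower, of which 4770 were among the 4804 and had the same direction, and RAP2A was lower by a log2 difference of -0.92 (SE 0.11, adjusted p = 2.4e-05). That value is of the brighter probe set, and on the second 1 of the 2 arrays labelled miR-376a*A that remain (578) lay within the range of miR-376a*G (562 to 615). RAP2A also passed without the array labelled miR-376a*A replicate 1 alone (-0.92, adjusted p = 0.0323). The share of calls that were higher was 43.0% as deposited, 65.7% after centring arrays on their medians (2848 higher and 1490 lower), 7.42% with the hybridisation controls and 27.0% with the poly-A controls. The median of all genes was -0.14 as deposited, 0.07 after centring, -0.82 with the hybridisation controls and -0.32 with the poly-A controls.

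**Figure D4:**
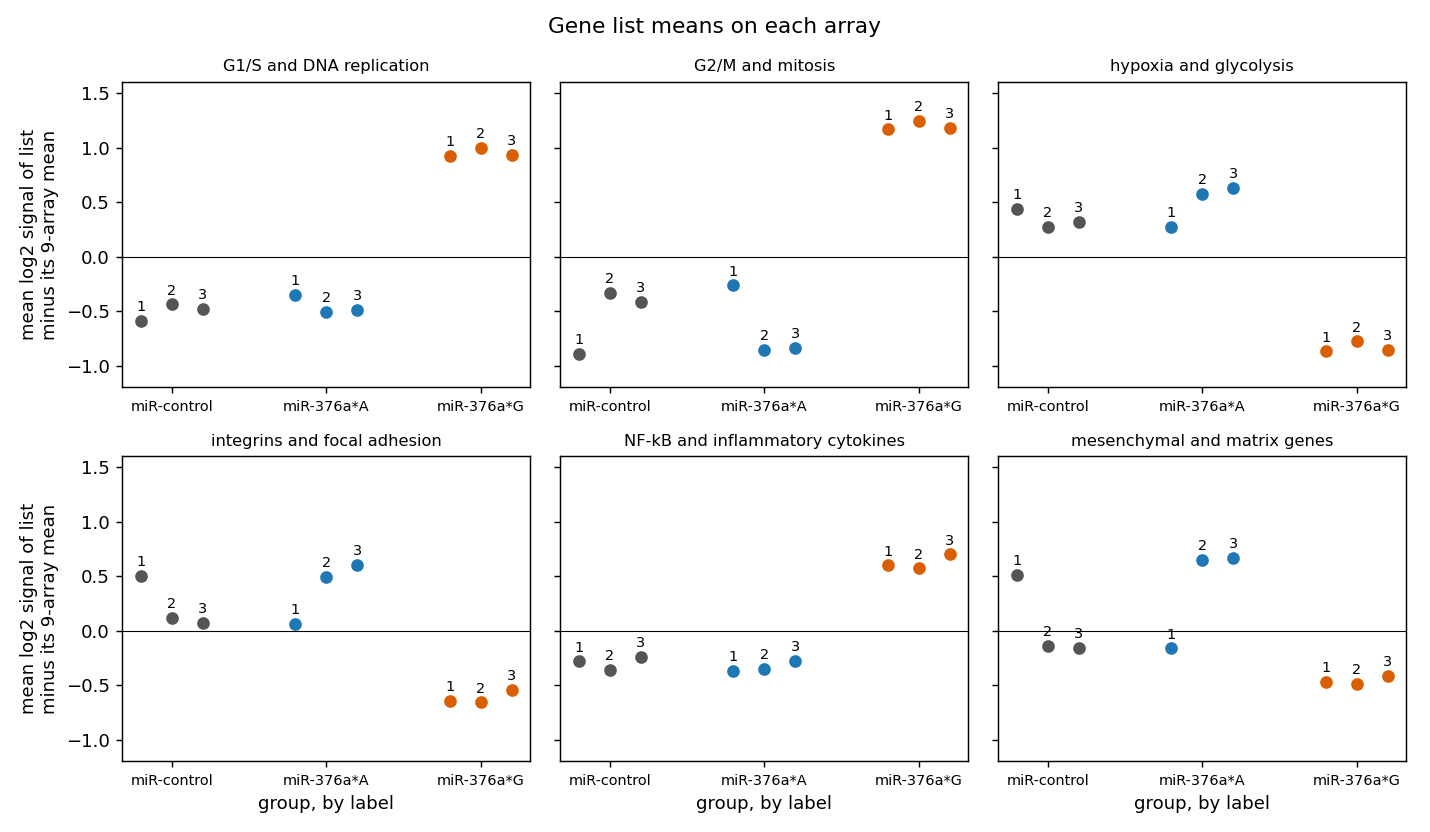
Mean log2 signal of 6 gene lists on each array, minus the mean of that list over the 9 arrays, by labelled group; points are arrays, numbered by replicate. For G2/M and mitosis the 3 arrays labelled miR-376a*G lie at 1.17 to 1.25 and the other 6 between -0.89 and -0.26.

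Over the 3 groups 4280 genes differed by limma's moderated F test, and 9033 without the 2 arrays that stood apart. The fold changes of the 2 forms against their shared control correlated at r = -0.0159 across genes, with a covariance of -0.0033. Unchanged groups simulated with shared controls and the spread of the arrays as labelled gave 0.502 and 0.0377. Those draws were independent between arrays, whereas the deviations of the 2 arrays that stood apart correlated at r = -0.88 across genes. The simulated values are therefore no sure reference for the labelled ones. Without the 2 arrays the correlation and covariance were 0.218 and 0.113, against 0.547 and 0.0195 in the simulation. As labelled, the comparisons shared 0 called genes, since miR-376a*A had 0 calls. A control arm of 3 arrays cannot be split into parts of 2 arrays, so part of any resemblance may come from the shared controls. The correlation moved to 0.226 without control replicate 1 and stayed between -0.0496 and 0.0447 without any other single array.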

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

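Every test in this part was chosen after the results it bears on had been seen.

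The arrays also carry probe sets for which the probe table lists no gene. Of 4026 that passed the same filter, 754 were called between miR-376a*G and control, 426 higher and 328 lower, against 0 between miR-376a*A and control and 1025 between the 2 forms (380 higher and 645 lower). Without the 2 arrays weighed next these counts were 1629, 930 and 1671. The transcripts they measure are not named here.

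The array labelled miR-376a*A replicate 1 lies with control replicates 2 and 3, and the array labelled control replicate 1 with miR-376a*A replicates 2 and 3. On a line from 0, the mean of control replicates 2 and 3, to 1, the mean of miR-376a*A replicates 2 and 3, the first lies at 0.0129 and the second at 0.926, where an exchange of the 2 samples would put them. A failed transfection of miR-376a*A replicate 1 alone would leave control replicate 1 near 0 rather than at 0.926, and a batch shared by arrays numbered 1 would make their deviations correlate positively, whereas they correlate at r = -0.881. Mean levels of the spiked controls follow the labels (exact permutation p = 0.1 between groups, the smallest possible), but the Dap 3′ to 5′ ratio does not (1.93 on the first array and 2.41 on the second; exact permutation p = 0.9), so whether an exchange came before or after the spikes were added stays open. An unrecorded factor that divided these arrays in the same way would give the same positions, so they do not single out an exchange. No record of sample handling was used here, and arrays were not renamed.

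The difference between miR-376a*G and the other 2 groups spans 4205 genes against control, with G2/M genes higher and hypoxia and integrin genes lower, lists that did not hold with an estimated correlation (adjusted p = 0.213, 0.213 and 0.244). Scaled to the hybridisation controls, 76.2% of the calls against control held, with all 2268 higher calls but 936 of 1937 lower ones kept. That scaling moves all genes alike and so sets which calls are kept. Quantile normalization kept 95.5% of the calls, with 0 called the opposite way. Cell cycle lists stayed higher, and hypoxia and integrin lists lower, under every other scaling tried. A shift of all genes alike cannot give both directions, which argues against scaling as their source. How far scaling sets the number of single calls in each direction stays open. RNA degradation would have raised the GAPDH 3′ to 5′ ratio, which was -0.0733 against control. Lower cell density or fresher medium could also bring proliferation up and hypoxia genes down (median -1.23), and with no record of density or batch this stays open beside an effect of the edited microRNA. Culture records, or a repeat with groups plated together, would separate them.

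Dividing the 6 arrays of a comparison into other groups of 3 shows how far the labels matter. Between miR-376a*A and control 10 of 10 divisions gave at least the labelled 0 genes, as any count must, so this says nothing about chance. The highest, 6295, set miR-376a*A replicate 1 with control replicates 2 and 3, which points to the structure of the samples already described and is no separate evidence for it. For miR-376a*G against control only the labelled division did (1 of 10; 4205 genes, highest other 0), as between the 2 forms (1 of 10; 4804, highest other 0), and 10 divisions are too few for a share under 0.05. Over 3 groups, 3 of 100 divisions reached the labelled 4280 genes, the others with 9679 and 4720, and both kept the miR-376a*G arrays together.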

How the results depend on the processing

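With array weights 5513, 7866 and 7866 genes were called for miR-376a*A against control, miR-376a*G against control and miR-376a*A against miR-376a*G, and 9902 over the 3 groups. Those weights were lowest for the arrays labelled miR-376a*A replicate 1 and control replicate 1. Without both arrays that stood apart, chosen after seeing them, the counts were 5269, 7067, 7508 and 9033. Hybridisation scaling gave 6575 for miR-376a*G (5639 higher, 936 lower), 8927 between the forms (662 and 8265) and 8262 over the groups. The replicate number as a block gave 2743 over the groups. Leaving out single arrays gave 0 to 0, 2994 to 4952, 3497 to 5602 and 2714 to 5691; the lowest came without miR-376a*G replicate 3 for 2994 and replicate 1 for 3497 and 2714. Total counts under the other filters, normalizations, pseudocounts and tests stayed within 1.5-fold, but not those by direction, such as 1285 higher for miR-376a*G and 1490 lower between the forms after median centring.

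Lists passing numbered 5, 8 and 9, and 0, 1 and 1 with an estimated correlation. For miR-376a*A against control they were 4 to 9 when single arrays were left out and 9 without both arrays. The agreement of the forms was 0.136 without a filter, 0.218 without both arrays, and -0.0496 to 0.226 without single arrays.

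For miR-376a*A against control RAP2A, at 0.00 as labelled, was called lower with array weights (-0.46) and without both arrays (-0.66). For miR-376a*G against control signs reversed with hybridisation scaling, which moves all genes alike, in CTSB (0.0568), RAP2C (0.0139), TFRC (0.17) and PGK1 (0.0563). They also reversed with poly-A scaling in TFRC (0.0727), and with the mean of probe sets in DICER1 (0.13) and HK2 (0.18). Between the forms they reversed with hybridisation scaling in MMP2 (-0.0265), CTSB (-0.29), RALB (-0.14), DICER1 (-0.17), TFRC (-0.28), PGK1 (-0.12) and YWHAZ (-0.15), in CSPG4 without both arrays (0.43) and in PECAM1 with the mean of probe sets (1.59). Of 95 called named genes per comparison, leaving out single arrays weakened 11 for miR-376a*G against control and 4 between the forms, the other settings chosen in advance 18 and 16, and those added later 14 and 8. Seed-match tests and their alternatives were not run.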

Other observations

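Both readings here were chosen after the results had been seen, and their p-values are not independent of the choice of arrays.

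Without the arrays labelled miR-376a*A replicate 1 and control replicate 1, miR-376a*A and control differ in 5269 genes, with RAP2A lower (-0.66, adjusted p = 9.9e-04). CEMIP (4.32) and IGFBP1 (3.78) are higher, and SCML1 (-3.78) and ELOVL5 (-3.56) lower. Of 25 mesenchymal and matrix genes 22 are higher and 2 lower (median 0.64, adjusted p = 6.4e-08, and 0.0668 with an estimated correlation), such as ACTA2 (2.22) and CDH2 (2.19), while markers of other cell types rose as well, in 2 of 2 leukocyte, 2 of 3 endothelial, 2 of 4 astrocyte and 2 of 6 neuronal genes, with 0, 0, 1 and 1 lower. Of 32 G2/M genes 18 are lower and 2 higher (median -0.46, adjusted p = 7.4e-05, and 0.262), such as HMMR (-2.21). If an exchange is what happened, the unedited form could raise mesenchymal genes as part of a broader change, with 9 lists passing at the preset correlation and 0 with an estimated one; genotyping cannot tell samples of 1 cell line apart, so the duplex itself would have to be measured in the remaining RNA.

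On the same arrays the 2 forms share 997 genes higher and 1126 lower than control, while 580 and 712 go opposite ways. Independent lists of the same sizes would share 745 and 719, with 596 and 898 going opposite ways. Both sets of calls use the same control arrays, so independent lists are not a no-effect reference. No overlap expected from the shared controls alone was computed. The fold changes of the 2 forms correlate at 0.218, and unchanged groups that share controls at 0.547. Changes particular to either form lower a correlation, so the smaller value does not mean less resemblance. The covariance (0.113) is above the simulated 0.0195. Parts of the shared set may be overlap of unrelated lists, or come from the shared controls or from transfection of an active duplex. Another part may come from targets outside the edited position. Seed matches were not tested here. They bear on targets and could not tell the shared controls from a response to transfection.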
